A study of Mus musculus with 1000 samples.

How the data were processed

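RNA was measured by 3' end sequencing in 1000 mouse brain libraries. The submitters' processing notes name GSNAP, a read aligner, and the mouse build GRCm38; GSNAP's version, its settings and the counting method are not given in the sources used here. The deposited file used here holds a list of 23231 distinct library names, each assigned by the authors to 1 of 3 expression tables. The part name is a category with no unit. Neither the library names nor the part names are measured values, and the list's remaining column is a running number. Of its names, 22231 belong to no library of this series and were not used.

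Groups were taken from the labels' candidate gene and genotype fields. Family number, mouse number, plate row, plate column, plate code and pool number were read from each library's title. The labels do not define these codes. Mice that share a family number are called siblings here, and their dams and litters were not examined. A pool was a combination of plate code and the number after the letter S. These readings were checked against each other by numbering the pools at 8 rows per plate. The pool number gave the plate row of the title for 1000 of 1000 libraries. Libraries of a pool share both codes, so this checks 84 pools rather than 1000 separate cases. The pool number also gave a single plate number for each of the 20 plate codes. The 4 codes with 1 family of this series could give no other result. All 1000 titles were found once in the list by exact match, and all pointed to table part 2.

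The 2 labelled amino acid changes were placed on the GENCODE M21 annotation, whose build is the GRCm38 named by the submitters' processing notes. Coding transcripts with a complete start were used, residues were counted from 1 at the start codon, and codons were read from the annotated transcript sequences. The codon step was tested on simulated exons of both strands. This placement was chosen after the file was seen to hold no expression values. The reference is the C57BL/6J strain per its assembly table, while the founders were C57BL/6NCrl per the labels' protocols.

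The edgeR comparisons of the Kmt2a homozygote and of the Dpp3 heterozygote with their siblings, planned before the data were examined, needed gene counts and were not run. The rule for named genes and its lists of microglial, interferon, astrocyte, immune and other cell type markers needed them too, so no list has a result. Depth per library is unknown here, and no interval, error or p-value is given. Counts of libraries, families and pools are exact counts of labels. The work used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.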

Results

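No expression value was analysed here: the only processed file used was a list that assigns each library name to 1 of 3 expression tables, and those tables were not used. The gene levels, fold changes, sequencing depths and replicate errors of this screen are therefore not reported. What follows describes the libraries, the comparisons their labels set up, and the annotated positions of the 2 labelled mutations.

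The series held 1000 RNA libraries from mouse brain without the cerebellum, made with a 3' end cDNA method in which short tags mark the mouse of origin inside a shared pool. The mice descended from males treated with ENU (N-ethyl-N-nitrosourea), a chemical that introduces point mutations, and were bred so that new mutations could become homozygous. Per the series' design text, the screen looked for altered inflammatory states in brain RNA and then for candidate mutations by exome sequencing. Library names carried 84 different numbers after the prefix ENU, treated here as family numbers. Of these families, 83 contributed 12 libraries to this series and 1 contributed 4 libraries. Whether names in the list outside this series include more libraries of the family of 4 was not examined.

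The labels placed 36 of the 1000 libraries, from 3 families, in a described group. The other 964 libraries, from 81 families, carried no genotype, phenotype or candidate gene and entered no comparison. A key genotype was given for 13 libraries and a primary phenotype for 2 libraries.

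Kmt2a, which encodes a histone H3 lysine methyltransferase, was the candidate gene of 1 family. One of its 12 libraries was labelled homozygous (m/m) for E899G, with the phenotype "Low MG signature", an abbreviation the labels do not spell out. The other 11 siblings carried the family's candidate label without a genotype. The comparison this sets up is 1 homozygote against 11 siblings of unstated genotype, so the homozygous arm has no replicate.

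Dpp3, which encodes the peptidase dipeptidyl peptidase III, was the candidate gene of another family of 12 libraries. One library was labelled heterozygous (m/+) for S194R with the phenotype "DAM", likewise not spelled out, and the other 11 siblings were labelled wild type (+/+). The comparison is again 1 library against 11, with no replicate of the mutant genotype and no homozygote among the 12. Per the design text, the screen sought altered states in brain RNA before candidate mutations. Whether the phenotypes of the Kmt2a homozygote and the Dpp3 heterozygote were called from these same libraries was not examined. If so, comparing their expression with siblings would not be independent of how these mice were chosen. The remaining labelled family supplied 12 libraries marked as unaffected.

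In the GENCODE M21 annotation of GRCm38, Kmt2a (ENSMUSG00000002028.13) lies on the minus strand of chromosome 9, from 44803355 to 44881296. The residue numbered in E899G, counted from 1 at the start of the protein, is reached in 3 annotated coding transcripts. Glutamate, the residue that E899G replaces, is at that position in 1 of the 3, Kmt2a-203, where the codon spans 44847953 to 44847955 in exon 4. In Kmt2a-201 and Kmt2a-202, whose proteins have 3963 and 3966 residues, the residue of that number is serine, and the codon that encodes this glutamate in Kmt2a-203 encodes residue 866 in exon 3. The Kmt2a-203 model is incomplete at its 3' end and covers 1438 residues.

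Dpp3 (ENSMUSG00000063904.4) lies on the minus strand of chromosome 19, from 4907229 to 4928287. Residue 194 is reached in 1 annotated coding transcript, Dpp3-201, which encodes 738 residues over 18 exons. It is serine, the residue that S194R replaces, and its codon spans 4921226 to 4921228 in exon 6. A single base change of the annotated codon can give arginine in Dpp3-201 by 3 routes. In Kmt2a, glycine can be reached by 1 route both from the glutamate codon of Kmt2a-203 and from the serine codon of Kmt2a-201 and Kmt2a-202, so this does not separate the transcripts.

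Among the libraries of this series, each of the 84 families occupied 1 library pool, and each pool held 1 family. Here 0 families were split between pools and 0 pools mixed families. Within each of the 84 families, every library had its own plate column. Siblings thus shared a pool, so the Kmt2a and Dpp3 comparisons within families are free of differences between pools. The mutant side of each is 1 library in its own plate column, so its genotype cannot be told apart from that position. Any comparison between families, including either candidate family against the unaffected family, cannot be told apart from a difference between pools. The Kmt2a family was in row C, the Dpp3 family in row D and the unaffected family in row G of 3 different plates.

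**Figure D1:**
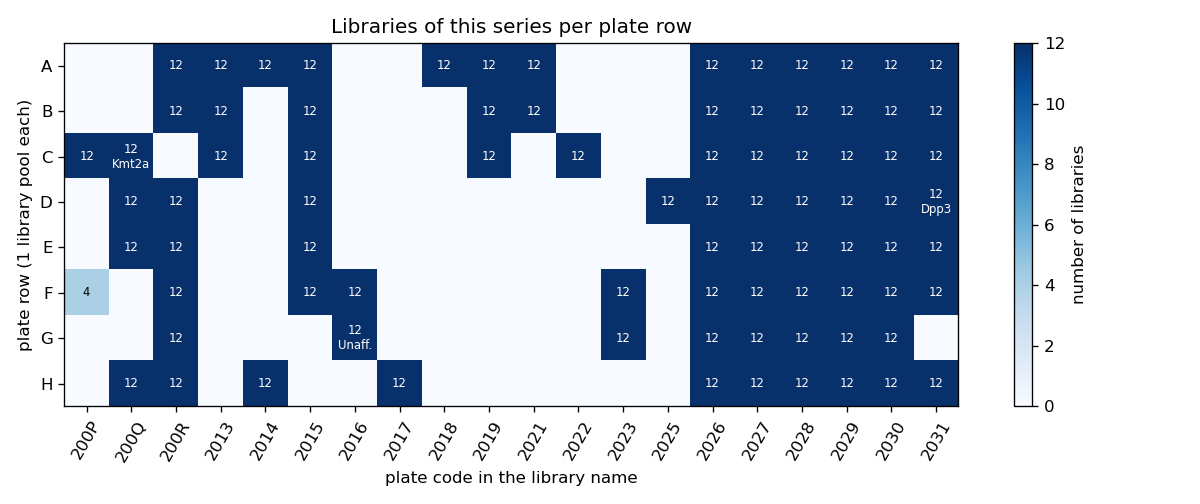
Number of libraries in each plate row (vertical axis) of each plate code (horizontal axis), with color and printed number both giving the count and white cells holding no library of this series. The rows of the Kmt2a, Dpp3 and unaffected (Unaff.) families are named, and each lies on a different plate; 83 of the 84 filled rows hold 12 libraries and 1 holds 4.

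The 20 plate codes held between 12 and 96 libraries of this series, and 5 plates were full, with 480 libraries in all. On 4 plates a single family of this series was present. Whether libraries outside this series shared the plates that were not full was not examined.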

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

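Counting pools by plate code and pool number together gave 84, the number of families. The pool number alone gave 72, because 12 of these numbers were each used by 2 pools, so the plate code is needed to identify a pool. Matching titles to the list of libraries found 1000 titles once with case and punctuation removed, and 1000 with the pool number and read suffix removed, as with the exact match. The alternatives planned for the Kmt2a and Dpp3 comparisons (DESeq2, no filter on low counts, leaving out each sibling) were not run, since no counts were analysed here. No paired analysis was run: no expression values were analysed here, and 1 library against 11 siblings gives no matched pairs.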

Other observations

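The test in this part was chosen after the result was seen. The label E899G does not match the longest annotated Kmt2a proteins, which have serine at that number, but matches Kmt2a-203. That transcript has a further exon of 99 bases (chromosome 9, 44878705 to 44878803 in GRCm38), or 33 codons, ahead of the codon, which accounts for the step from residue 866 to the labelled number. A candidate explanation is that the label follows the numbering of a transcript with this exon. The annotated transcripts place 2 different codons at the labelled number, and Kmt2a-203 was singled out because it matched. Glutamate makes up 84 of its 1438 residues, or 5.84%, which gives a chance of 11.3% that at least 1 of 2 codons is glutamate. The limit set for this chance lay below the 5.84% of a single codon, so a match could not have decided the explanation. A different numbering or an error in the label stays open. The mutation's genome position was not given in the labels used here, which would settle it.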
